A study of Mus musculus with 36 samples.

How the data were processed

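Messenger RNA was measured on whole-genome mouse expression arrays in the forebrain of 18 heterozygous Cnp–eGFP-L10a mice, in which oligodendrocyte ribosomes carry a tagged protein. Each animal gave 2 arrays: the immunoprecipitated bound fraction (oligodendrocytes) and the unbound remainder (neurons and other glia by the labels). The 36 arrays formed 6 groups of 6: sleep, waking and sleep deprivation in each fraction. Sleep animals were killed between 3 and 5 pm after at least 75% of the preceding 6 to 7 h asleep, and waking animals between 3 and 5 am after at least 70% of that window awake. Sleep deprived animals were kept awake for 4 h with unfamiliar objects in the light period. Sleep and waking therefore also differ in time of day, and sleep and sleep deprivation do not differ in light phase.

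The deposited values were log2 signals per probe set, made by the authors with RMA per the submitters' processing notes (the RMA version is not given in the sources used here). They were used as deposited, with no further normalization. Of 45101 probe sets, 34945 named 1 gene, 932 named several, 9160 listed none and 64 were array controls. Gene names of 34741 probe sets were looked up through their Entrez identifiers, which changed 0 symbols. One probe set per gene was kept, the one with the highest mean, for 18193 genes, and 13924 genes were tested after a filter that kept a gene whose mean reached the 40th percentile of all probe sets in at least 1 fraction (4.471 log2 in the bound and 5.183 log2 in the unbound arrays). Among tested genes, 8141 had several probe sets.

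All tests used limma 3.58.1 in R 4.3.3 with an intensity trend in the variance moderation (with the package data.table in version 1.17.8; figures with Python 3.11.15, matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6). The 3 state contrasts of a fraction came from a group-means model of its 18 arrays. Bound against unbound, and the difference of a state change between the fractions, were tested on the per-animal difference of the 2 arrays. The labels give both fractions of an animal the same number, so this pairing, the animal block, comes from the design. The deviations of the 2 arrays of an animal from their group means correlated by −0.0032 to 0.0848 (mean 0.0458 against −0.00904 for arrays of other animals), and 12 of 18 animals matched best with their own other array. Without the animal block, 11623 genes were called between the fractions instead of 11642, and the fraction differences gave 868 instead of 744 genes (waking) and 943 instead of 869 (sleep deprivation).

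A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within a contrast. Genes changed the same way in waking and sleep deprivation had to pass both contrasts against sleep in 1 direction. Genes that set waking apart had to pass waking against sleep and waking against sleep deprivation in 1 direction. Because these pairs of contrasts share a control group, the overlap was compared with 50 simulations of unchanged groups and with 20 splits of the control group into separate parts. Unchanged groups give almost no calls, so their shared count sets no standard and only their covariance serves as a comparison. Standard errors are those of limma, and values in figures and group means are given with the standard deviation over 6 animals.

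In total, 26 gene lists (433 genes, 392 matched) were written before the data were examined: core clock, immediate-early, unfolded protein response, heat shock, glucocorticoid response, cholesterol synthesis, phospholipid synthesis, fatty acid and myelin sphingolipid synthesis, myelin and mature oligodendrocyte, oligodendrocyte precursor, oligodendrocyte lineage regulators, cell cycle, apoptosis, cytosolic ribosomal proteins, mitochondrial oxidative phosphorylation, antigen presentation and interferon, neuron, astrocyte, microglia, endothelium, mural cell, choroid plexus and ependyma, striatal neuron, hypothalamic peptide neuron, sex-linked, and red blood cell (2 genes measured, too few to test). Lists were tested with camera at an inter-gene correlation of 0.01, adjusted over all lists and contrasts of a fraction, and a list is said to be called when camera called it. Members called in a contrast are counted after adjustment over all genes and, where stated, over the list alone.

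Named genes followed a rule written before the data were examined: the 6 largest rises and 6 largest falls for bound against unbound and for each bound state contrast, 4 and 4 for unbound contrasts and fraction differences, 8 per direction for the sets changed the same way or set apart, ranked by the smaller of their 2 changes, up to 4 members of each list with the smallest p, and Cnp and Rpl10a as the genes of the transgene. Uncharacterised symbols were skipped. The samples, the tests, the named-gene rule and most alternatives were all fixed before the data were examined.

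Alternatives fixed at that point were quantile normalization over all 36 arrays or within a fraction, no filter or a 60th percentile filter, a mean of all probe sets of a gene, no intensity trend, array weights, a minimum change of 1.2-fold, only the 2 states compared, the replicate number as a block, no animal block, leaving out each array or animal in turn, and for lists an estimated inter-gene correlation and fry. One alternative was chosen after seeing the data: leaving out 3 animals set apart by sex-linked genes. The pipeline was tested on simulated data with 200 changed genes among 13924: at a change of 1 log2 it recovered 80.6% in bound waking against sleep, 71.6% in unbound waking against sleep and 53.7% in the fraction difference in waking, and at 0.5 log2 28.4%, 37.3% and 7.46%. Between 1.43% and 8.49% of calls were false in these simulations. They drew independent noise for each gene with no offset between groups, so these shares do not cover calls that such offsets could give. Replicate arrays correlated at 0.9508 to 0.9832. Scanner files were not used here, so no alternative background correction was run.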

Results

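Messenger RNA was profiled on 36 expression arrays from the forebrain of 18 Cnp–eGFP-L10a mice, in which ribosomes of oligodendrocytes, the myelin-forming cells, carry a tag and can be immunoprecipitated. The bound (oligodendrocyte) and the unbound (remaining cells) fraction of each animal were measured, with 6 animals in each of 3 states: sleep in the light phase, spontaneous waking in the dark phase, and 4 h of enforced wake in the light period. The number of arrays limits the precision of every value below. Of 13924 genes tested, 1318 changed between waking and sleep and 2005 between sleep deprivation and sleep in the bound arrays, against 1004 and 1089 in the unbound arrays.

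Array means were nearly equal within a group and differed between groups. They averaged 5.92, 5.93 and 5.91 log2 in the bound sleep, waking and sleep deprived arrays and 6.40, 6.34 and 6.41 log2 in the unbound arrays. The standard deviation within a group was 0.002933 to 0.009939 (n = 6). Such narrow groups would arise if each group had been normalized on its own, which the sources used here do not state, and every state comparison below crosses groups. Dim probe sets were called more often than probe sets of middle level: in bound waking against sleep, 28.4% were called in group 2 of 10 groups ordered by mean level from dim to bright. In group 7 it was 7.81% and in the brightest group 14.2%. Group 2 had the highest share in each of the 6 state contrasts, but the brightest group came near the dim ones in bound sleep deprivation against sleep (21.6%, group 1 at 22.5%). In unbound sleep deprivation against waking it passed group 1 (23% and 21.2%). Among 155 probe sets of receptor and germline genes not expressed in brain, 23.2% were called in bound waking against sleep, against 9.77% of 16574 bright probe sets. Several of the large changes named below lie at such levels, for example Tfpi in the bound arrays with 4.48 log2 in sleep and 2.72 in waking. Egr2 averaged 3.80 log2 in bound sleep, and genes not expressed in brain had a median of 3.03 over all 36 arrays. The size of the change of Egr2 in the bound arrays is therefore less certain than its standard error says.

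**Figure D1:**
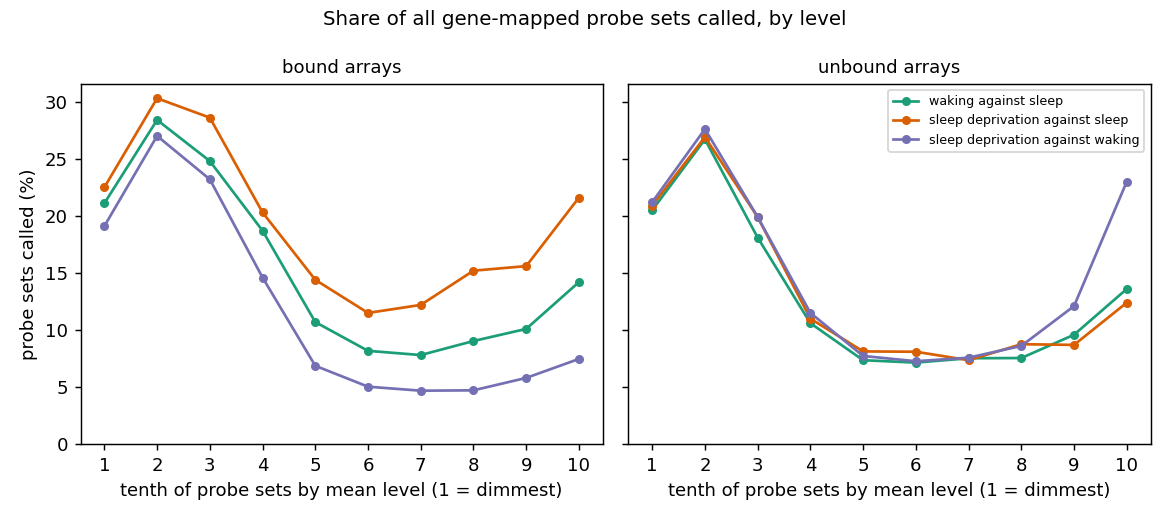
Percent of gene-mapped probe sets called in each state contrast, in 10 groups ordered by mean level, for the bound and unbound arrays. Called shares were highest in group 2 in every contrast.

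Bound against unbound arrays asked which messages the immunoprecipitation enriched. Myrf, a transcription factor of myelination, was 4.76 ± 0.09 log2 higher in the bound arrays (SE, n = 18 animals, adjusted p = 5.65e-20). Next came Casq1 at 4.44 ± 0.13, Tmem125 at 4.42 ± 0.10, Pdlim2 at 4.38 ± 0.06, Sgk2 at 4.22 ± 0.08 and Serpinb1a at 4.13 ± 0.10. Sh3rf2 (−4.40 ± 0.13 log2), Gdap10 (−4.01 ± 0.17), the long noncoding RNAs Miat (−3.96 ± 0.14) and Meg3 (−3.90 ± 0.11), the haemoglobin gene Hbb-b2 (−3.94 ± 0.10) and Ifit1bl1 (−3.92 ± 0.30) were lowest. All 12 genes moved in their direction in 18 of 18 animals. Cnp, whose promoter drives the tag, was higher by 1.24 ± 0.02 log2 (adjusted p = 1.36e-21), and Rpl10a, the gene of the tagged ribosomal protein, was lower at −0.52 ± 0.04 log2 (adjusted p = 6.7e-10).

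Every one of 17 myelin and mature oligodendrocyte genes was higher in the bound arrays (mean 2.70 log2, adjusted p = 1.76e-15). Mog stood at 3.94 log2. Fatty acid and myelin sphingolipid genes followed with 20 of 21 higher (mean 1.65, adjusted p = 5.47e-11), led by Fa2h at 3.87 and Cers2 at 3.59. Cholesterol synthesis genes had 14 of 19 higher and 4 lower (mean 0.44, adjusted p = 0.000969). All 16 neuron genes were lower (mean −1.30, adjusted p = 0.000577; adjusted p = 0.31 with an estimated correlation). All 14 astrocyte genes were lower (−1.95, adjusted p = 0.00258; adjusted p = 0.256 with an estimated correlation), and so were all 12 microglia genes (−2.29, adjusted p = 0.0185; adjusted p = 0.0844 with an estimated correlation). The 7 striatal neuron genes (−2.09, adjusted p = 0.0155; adjusted p = 0.0799 with an estimated correlation) and the 7 hypothalamic peptide neuron genes (−1.75, adjusted p = 0.044; adjusted p = 0.118 with an estimated correlation) were lower throughout. Glucocorticoid response genes were 9 higher and 4 lower of 15 (mean 0.64, adjusted p = 0.00373; adjusted p = 0.287 with an estimated correlation). The median of all genes lay at −0.35 log2 here and at 0.08 after quantile normalization over all arrays. Relative to the median the myelin list stood at 3.05, fatty acid and sphingolipid at 2.01, cholesterol at 0.80 and glucocorticoid response at 0.99. On the same scale neuron genes stood at −0.95, astrocyte at −1.59, microglia at −1.94, striatal at −1.74 and hypothalamic at −1.40.

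Of the lists that camera did not call between fractions, the immediate-early list was 3 higher and 15 lower of 20 (mean −1.21 log2), and the core clock list 3 higher and 13 lower of 17 (−0.80). Oxidative phosphorylation genes were 0 higher and 27 lower of 29, ribosomal protein genes 2 higher and 16 lower of 20, and precursor genes 4 higher and 10 lower of 15 (−0.49). Unfolded protein response genes were 9 higher and 3 lower of 17, heat shock genes 6 and 5 of 13, phospholipid synthesis genes 11 and 10 of 23, and lineage regulators 7 and 10 of 18. Cell cycle genes were 6 higher and 9 lower of 18, apoptosis genes 5 and 10 of 16, antigen presentation genes 3 and 9 of 13, endothelial genes 1 and 5 of 6, mural genes 0 and 6 of 6, choroid plexus genes 1 and 6 of 7 and sex-linked genes 1 and 1 of 4. With fry, which does not compare a list with other genes, all of these lists passed except heat shock (adjusted p = 0.442), phospholipid synthesis (adjusted p = 0.108) and sex-linked (adjusted p = 0.0673). The means of the antigen presentation (−0.35 to 0.20), cell cycle (−0.34 to 0.14), endothelium, phospholipid and sex-linked lists changed sign under quantile normalization over all arrays. Median, mean and test differed in sign for the heat shock, phospholipid, precursor, lineage regulator, cell cycle and sex-linked lists. The 2 red blood cell genes measured, Hbb-b2 and Alas2, stood at −3.94 and −1.97 log2 and were not tested as a list. In total 11642 of 13924 genes were called, 3555 higher and 8087 lower. After quantile normalization over all arrays 6157 were higher and 5329 lower.

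**Figure D2:**
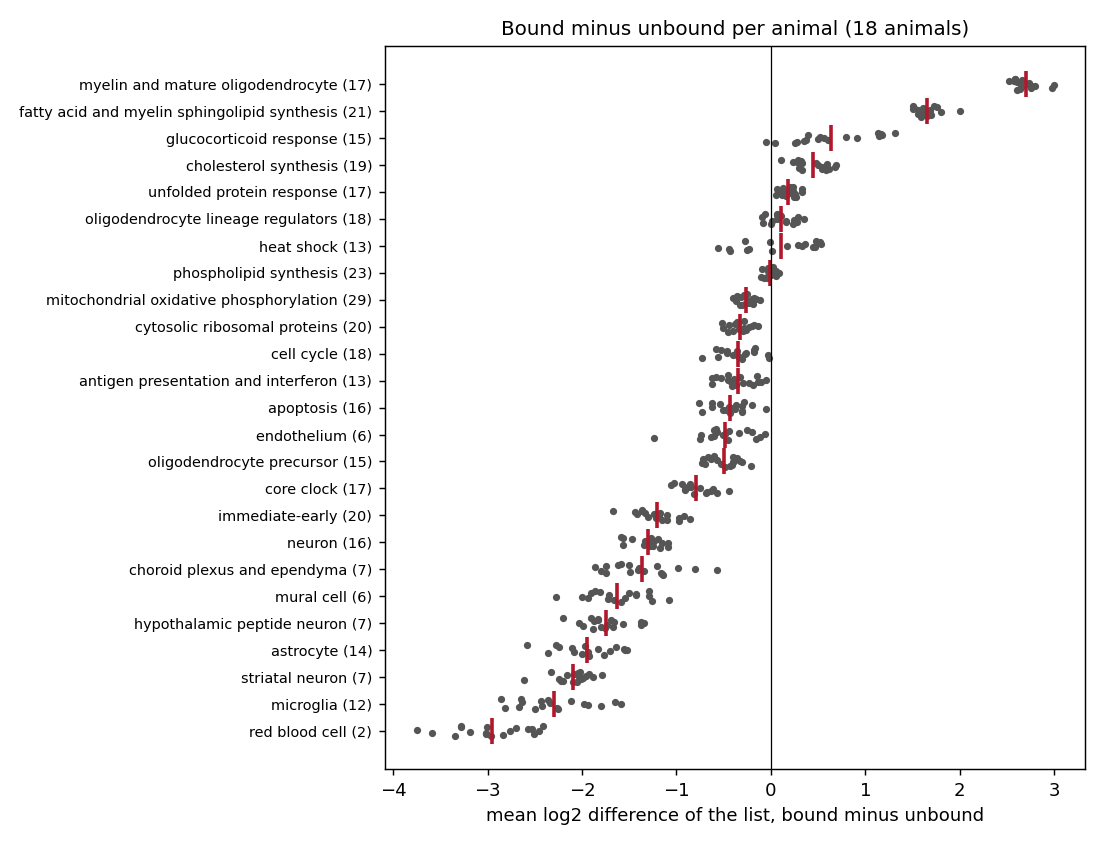
Mean of each list in the bound minus the unbound array of each animal (18 animals, red tick at the mean). The antigen presentation, cell cycle, endothelium and phospholipid means changed sign under quantile normalization over all arrays.

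Bound waking against sleep asked which messages of the bound fraction followed the animals' state, with time of day differing as well. The bound arrays still held neuron messages (neuron list at 11.01 log2 in bound and 12.29 in unbound sleep arrays). Plin4, a lipid droplet protein, rose by 3.58 ± 0.33 log2 (SE, n = 6 per group, adjusted p = 8.66e-06). The immediate-early transcription factor genes Egr2 and Fos rose by 3.54 ± 0.30 (adjusted p = 5.08e-06) and 2.69 ± 0.27 (adjusted p = 1.06e-05). The chaperone gene Hspa1b rose by 3.19 ± 0.75 (adjusted p = 0.0114) and Scrg1 by 2.38 ± 0.29 (adjusted p = 7.4e-05). Krt18 (−2.19 ± 0.26 log2), Zfp28 (−2.02 ± 0.48), Fgf5 (−1.89 ± 0.37), Popdc3 (−1.86 ± 0.32), Tfpi (−1.76 ± 0.45) and the transcriptional coactivator Yap1 (−1.68 ± 0.23) fell most. Of 12 genes named by rule here, 11 moved in their direction in all 6 animals and Tfpi in 5 of 6. No overlap between the groups was seen for 10. Chance gives 0.216% for a gene picked without regard to its change, but genes named here and below were picked as the largest changes, so this share does not test them. Sult1a1, also named by rule, rose by 1.87 ± 0.55 (adjusted p = 0.0369) and was no longer called without 3 animals that sex-linked genes set apart (adjusted p = 0.183).

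Immediate-early genes rose as a list: 9 of 20 rose and 1 fell (10 and 1 adjusted over the list alone). Their mean change was 0.70 log2 (adjusted p = 6.85e-08), with Nr4a1 at 1.38 ± 0.14 and Egr1 at 1.2 ± 0.14. Of 13 heat shock genes, 8 rose and 0 fell (11 and 0 over the list alone). On average they moved by 0.81 log2 (adjusted p = 6.48e-11; adjusted p = 0.148 with an estimated correlation), among them Chordc1 at 0.96 ± 0.12 and Hsph1 at 0.82 ± 0.11. Glucocorticoid response genes, which include Plin4 and Sult1a1, gave 4 rises and 0 falls among 15 (5 and 0 over the list alone). The list's mean was 0.73 log2 (adjusted p = 0.000364; adjusted p = 0.716 with an estimated correlation). The unfolded protein response list rose by a mean of 0.19 with 2 of 17 genes called (2 over the list alone; adjusted p = 0.0426; adjusted p = 0.889 with an estimated correlation). The myelin list was not called by camera (mean −0.10, adjusted p = 0.0978) but passed with fry (adjusted p = 0.00382), and 5 of its 17 members fell and 1 rose (7 and 2 over the list alone). Pllp fell by 0.75 ± 0.08, Opalin by 0.77 ± 0.10, Mag by 0.27 ± 0.05 and Cnp by 0.09 (−0.05 and not called after quantile normalization within the fraction, adjusted p = 0.13), while Mobp rose by 0.21. Among core clock genes, 1 of 17 rose and 2 fell. Cry1 rose by 1.10 ± 0.15 (adjusted p = 0.00021), Nr1d1 changed by −0.71 ± 0.11 and Dbp by −0.87 ± 0.19, the last no longer called without the 3 animals (adjusted p = 0.0515).

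The remaining lists passed neither camera nor fry in this contrast. Cholesterol synthesis had 1 rise and 2 falls of 19, phospholipid synthesis 1 and 1 of 23, and fatty acid and sphingolipid synthesis 0 and 1 of 21. Precursor genes had 1 and 0 of 15, lineage regulators 2 and 0 of 18, cell cycle genes 1 and 0 of 18 and apoptosis genes 1 and 0 of 16. Oxidative phosphorylation had 0 and 1 of 29, astrocyte 2 and 0 of 14, endothelium 1 and 2 of 6 and striatal neuron 2 and 0 of 7. Ribosomal protein, antigen presentation, neuron, microglia, mural, choroid plexus, hypothalamic and sex-linked lists had 0 called members. Median, mean and test differed in sign for the clock, cholesterol, precursor, endothelium, choroid plexus and striatal lists. In total 651 genes rose and 667 fell, 200 of them at least 2-fold. There were 684 called genes without the 3 animals. Of called genes with a second tested probe set, 76.6% of 282 moved the same way in it (95% interval 71.2 to 81.4%, exact), against 60.1% of uncalled genes.

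Bound sleep deprivation against sleep compared 2 groups in the light period. Cdkn1a, an inhibitor of the cell cycle, rose by 4.60 ± 0.50 log2 (SE, n = 6 per group, adjusted p = 6.76e-06), and Plin4 by 4.31 ± 0.33 (adjusted p = 1.82e-07). Hspa1b rose by 3.99 ± 0.75 (adjusted p = 0.00145) and Scrg1 by 3.33 ± 0.29 (adjusted p = 7.8e-07). The sulfotransferase gene Sult1a1 rose by 3.32 ± 0.55 (adjusted p = 0.000448) and Egr2 by 3.25 ± 0.30 (adjusted p = 1.46e-06). Plin4 averaged 5.81 ± 0.49 log2 in sleep, 9.39 ± 0.68 in waking and 10.12 ± 0.69 in sleep deprivation (SD, n = 6). Gpr135 (−2.28 ± 0.39), Nt5dc1 (−2.25 ± 0.24), Tfpi (−2.25 ± 0.45), the growth factor gene Btc (−2.17 ± 0.26), Cabcoco1 (−2.11 ± 0.32) and Saxo2 (−2.08 ± 0.38) fell most. Counted against the sleep mean, 11 of the 12 genes clearly moved in their direction in 6 of 6 animals. Hspa1b stood at its sleep mean in animal 11 (6.32 log2, other sleep deprived animals 9.16 to 11.92), below sleep animals 2 (8.19) and 4 (7.39), and 10 genes showed no overlap. A second probe set of Gpr135 changed by −0.04 only, and Saxo2 was no longer called with the mean of its probe sets (adjusted p = 0.0567).

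Glucocorticoid response genes rose almost without exception: 14 of 15 rose and 0 fell (15 and 0 over the list alone). As a list they averaged 1.92 log2 (adjusted p = 4.14e-17; adjusted p = 0.118 with an estimated correlation), with Fkbp5 at 3.20 ± 0.30, Zbtb16 at 2.71 and Errfi1 at 1.01 ± 0.12. Of 13 heat shock genes 11 rose and 0 fell (12 and 0 over the list alone). Their mean change was 1.05 log2 (adjusted p = 1.43e-12; adjusted p = 0.118 with an estimated correlation). Of 20 immediate-early genes 11 rose and 1 fell (12 and 2 over the list alone). On average they moved by 0.81 log2 (adjusted p = 4.7e-08), with Fosl2 at 1.68 ± 0.16. Unfolded protein response genes gave 9 rises and 0 falls among 17 (12 and 0 over the list alone). The list's mean was 0.46 log2 (adjusted p = 1.52e-06; adjusted p = 0.298 with an estimated correlation), including Herpud1 at 1.13 ± 0.19, Xbp1 at 0.88 ± 0.19 and the chaperone genes Hspa5 at 0.73 and Calr at 0.47 ± 0.09. Myelin genes gave 3 rises and 3 falls of 17 (4 and 6 over the list alone). As a list they averaged −0.07 log2 (adjusted p = 0.701). Opalin fell by 0.88 ± 0.10, Pllp by 0.66 ± 0.08 and Aspa by 0.41 ± 0.05. Mobp rose by 0.40 ± 0.07, Myrf by 0.41 and Mbp by 0.11. Cholesterol synthesis genes had 0 rises and 3 falls of 19, with Dhcr7 at −0.63 ± 0.12. The list (mean −0.17, adjusted p = 0.0606) passed after quantile normalization within the fraction and with fry (adjusted p = 0.0205). Core clock genes had 0 rises and 2 falls, Dbp at −0.84 ± 0.19 and Ciart at −0.84 ± 0.20. Precursor genes had 1 rise and 2 falls, with Lhfpl3 at −1.33 ± 0.25.

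No list of another cell type passed camera or fry in this contrast. Median, mean and test differed in sign for the phospholipid, lineage regulator, ribosomal, neuron, astrocyte, microglia and endothelium lists. The phospholipid, ribosomal and astrocyte means changed sign under quantile normalization. In total 1048 genes rose and 957 fell, 359 of them at least 2-fold. Of all genes 1799 were called without the 3 animals. Second probe sets of called genes moved the same way in 81.4% of 537 genes. Genes at least 2-fold enriched in the bound arrays were called more often (26.9% of 1245) than those at least 2-fold depleted (11.4% of 3766), a difference that was not tested.

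**Figure D3:**
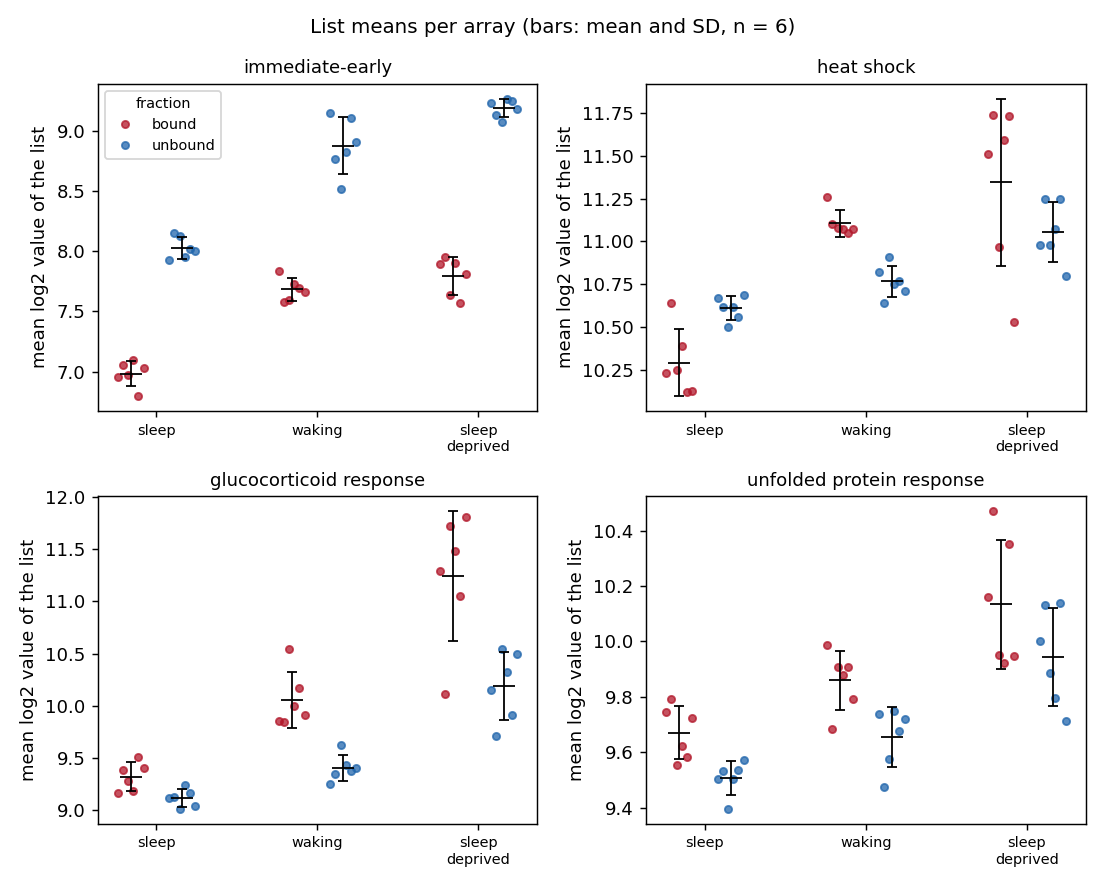
List means of the immediate-early, heat shock, glucocorticoid response and unfolded protein response genes on each array, with mean and SD of 6 arrays, by state and fraction.

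**Figure D4:**
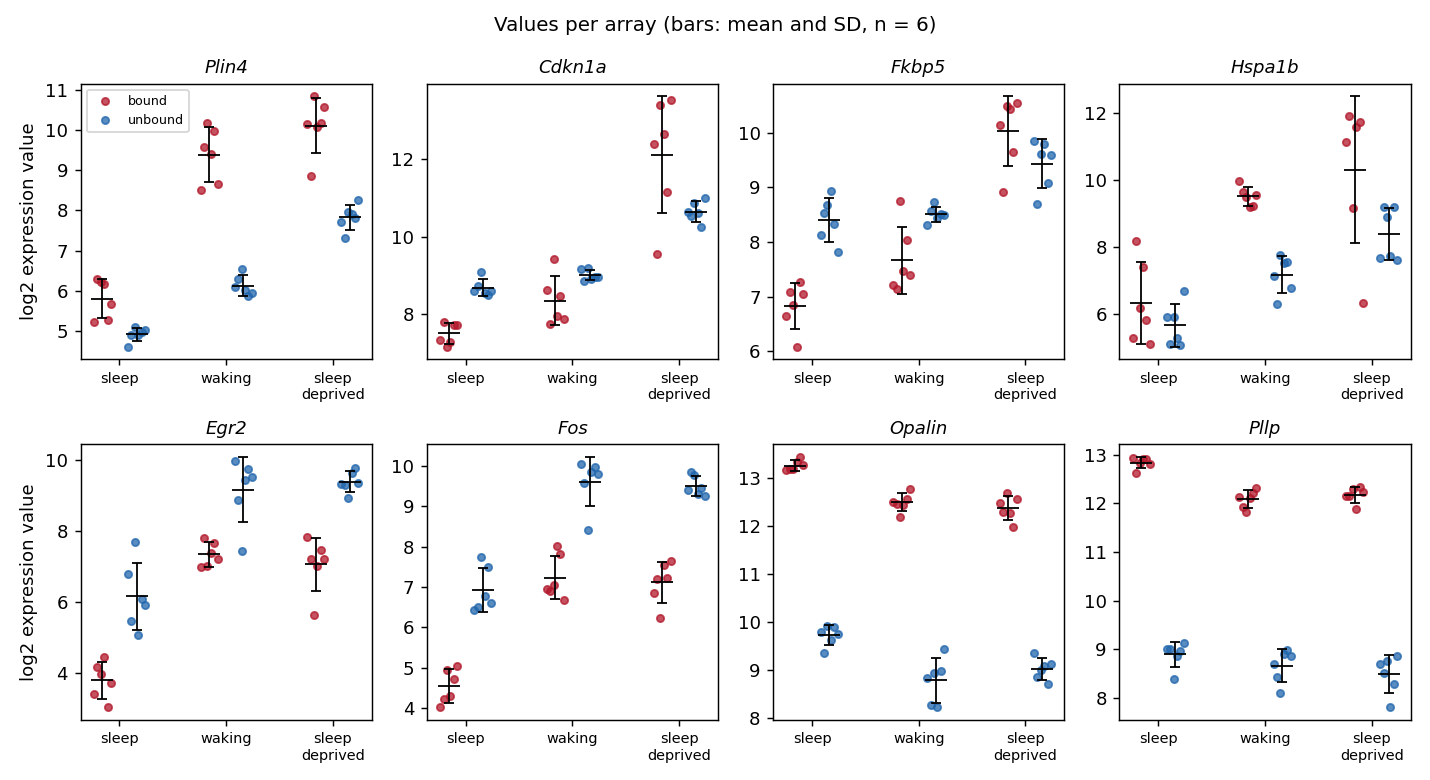
Levels of Plin4, Cdkn1a, Fkbp5, Hspa1b, Egr2, Fos, Opalin and Pllp on each array, with mean and SD of 6 arrays, by state and fraction.

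Bound sleep deprivation against waking compared enforced with spontaneous wake, again at different times of day. Cdkn1a was higher by 3.75 ± 0.50 log2 after sleep deprivation (SE, n = 6 per group, adjusted p = 0.000408). Fkbp5, a cochaperone of the glucocorticoid receptor, was higher by 2.36 ± 0.30 (adjusted p = 0.00032), Zfand4 by 2.33 ± 0.49 (adjusted p = 0.00952) and Rhoj by 2.12 ± 0.32 (adjusted p = 0.00138). Myh11 (2.19 ± 0.45, adjusted p = 0.00771) and Ada (2.15 ± 0.46, adjusted p = 0.0104) were also higher but were not called without the 3 animals (adjusted p = 0.0555 and 0.0649). The potassium channel subunit gene Kcne4 was lower (−2.19 ± 0.19, adjusted p = 6.84e-06), as were Cabcoco1 (−2.04 ± 0.32), Atp8b1 (−1.93 ± 0.34) and Zfp599 (−1.85 ± 0.33). Dnah7a (−2.01 ± 0.45) lost its call without the 3 animals (adjusted p = 0.127), and Cxadr (−1.81 ± 0.38) with the mean of its probe sets (adjusted p = 0.267), its second probe set changing by 0.17. All 12 genes moved in their direction in 6 of 6 animals, and 9 showed no overlap.

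Glucocorticoid response genes were again higher, 9 of 15 with 0 lower (14 and 0 over the list alone). Their mean change was 1.19 log2 (adjusted p = 9.9e-14; adjusted p = 0.148 with an estimated correlation), including Zbtb16 at 1.90 ± 0.33. The unfolded protein response list was higher (mean 0.27, 1 of 17 called and 4 over the list alone; adjusted p = 0.00141; adjusted p = 0.645 with an estimated correlation), with Calr at 0.46 ± 0.09. Cholesterol synthesis genes were lower as a list (mean −0.16, adjusted p = 0.0426; adjusted p = 0.645 with an estimated correlation), with 0 of 19 members called, and this call was also lost with fry and with the mean of all probe sets. Heat shock genes (mean 0.24, adjusted p = 0.0644), immediate-early genes (4 of 20 higher, 0 lower, mean 0.11, adjusted p = 0.549) and microglia genes (mean −0.38, adjusted p = 0.0646; with fry, adjusted p = 0.0423) were not called as lists by camera. Cry1 was lower (−0.87 ± 0.15, adjusted p = 0.00264), Mbp higher by 0.15 ± 0.03 and the precursor gene Nkx2-2 lower (−0.65 ± 0.11, adjusted p = 0.00302). The call of Mbp was lost under quantile normalization (adjusted p = 0.198), and the means of the myelin and oxidative phosphorylation lists changed sign. In total 375 genes were higher and 323 lower, and 234 were called without the 3 animals. In a second probe set, 74.3% of 140 called genes moved the same way.

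Genes changed the same way in waking and in sleep deprivation, each against sleep, would include those that follow wake. An offset of the sleep arrays alone would give such genes too. There were 699 genes changed the same way in the bound arrays, 366 higher and 333 lower. Besides Plin4, Egr2, Hspa1b, Fos, Scrg1 and Sult1a1, the largest rises were Fam83d (1.69 ± 0.33 and 2.45 ± 0.33 log2, SE, n = 6 per group) and the phospholipase gene Pla2g3 (1.67 ± 0.40 and 3.06 ± 0.40), whose rise in waking was not called without the 3 animals (adjusted p = 0.0715). Krt18, Zfp28, Tfpi, Popdc3 and Yap1 fell in both, with Rfc3, a DNA replication factor (−1.65 ± 0.30 and −1.78 ± 0.30), Btc (−1.62 ± 0.26 and −2.17 ± 0.26) and the citrate transporter gene Slc13a5 (−1.61 ± 0.26 and −1.70 ± 0.26). The 2 contrasts share the sleep arrays: independent lists of these sizes would share 94.8 genes. Simulated unchanged groups shared 0, but such groups give almost no calls, so this count sets no standard for the overlap. Splitting the sleep arrays so that each contrast had its own left 97 to 127 genes. Each split contrast had fewer control arrays, so this count cannot be set against the 94.8. The covariance of the 2 changes was 0.0974, which exceeded the 0.0227 simulated from the shared arrays by 0.0747. With split controls, which share no array, it was 0.0739. Without the 3 animals 403 genes passed both contrasts. With all animals, 183 of these genes had a second probe set, and in 86.3% the mean of its 2 changes had the same direction. In 73 of them both of its changes also had an unadjusted p under 0.05.

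Genes that set waking apart from both groups in the light period would include those that follow time of day. Moxd1 was higher in waking than in sleep by 1.54 ± 0.31 log2 and changed by −1.64 ± 0.31 in sleep deprivation against waking. Kcne4 changed by 1.28 ± 0.19 and −2.19 ± 0.19, and the Notch target gene Hey2 by 1.25 ± 0.29 and −1.55 ± 0.29. Parp12 (−1.26 ± 0.23 and 1.37 ± 0.23) and Ikzf1 (−1.25 ± 0.24 and 1.26 ± 0.24) were lower in waking. The growth factor gene Fgf5 (−1.89 ± 0.37 and 1.97 ± 0.37) was lower as well, but its second contrast was not called without the 3 animals (adjusted p = 0.0555). In all 174 bound genes stood apart, 89 higher and 85 lower. Independent lists would share 33.1. Split waking arrays gave 2 to 9, but with fewer control arrays per contrast, so these 2 results cannot be compared. Simulated groups shared 0, which again sets no standard. The covariance was 0.0393, which exceeded the 0.0227 simulated from the shared arrays by 0.0166. With split controls, which share no array, it was 0.016. Without the 3 animals, 2 of which were waking, 45 genes passed both contrasts.

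Unbound waking against sleep gave the changes in the remaining RNA, which comes from neurons and other glia by the labels but still held oligodendrocyte messages (myelin list at 10.03 log2 in unbound and 12.76 in bound sleep arrays). Egr2 rose by 2.99 ± 0.40 log2 (SE, n = 6 per group, adjusted p = 0.000241) and Fos by 2.68 ± 0.26 (adjusted p = 7.44e-06). The synaptic gene Arc rose by 2.09 ± 0.17 (adjusted p = 1.16e-06) and the noncoding RNA Kcnq1ot1 by 1.85 ± 0.38 (adjusted p = 0.00633). Cfap52 (−1.94 ± 0.23), Galnt4 (−1.73 ± 0.14), Skor1 (−1.69 ± 0.39) and the checkpoint kinase gene Chek2 (−1.61 ± 0.21) fell most. All 8 moved in their direction in 6 of 6 animals, and 5 showed no overlap. Immediate-early genes rose as a list, 10 of 20 with 0 falls (12 and 0 over the list alone). On average they moved by 0.85 log2 (adjusted p = 1.06e-19). Core clock genes rose as a list, with 4 rises and 2 falls of 17 (7 and 2 over the list alone). The list's mean was 0.16 log2 (adjusted p = 0.00408; adjusted p = 0.15 with an estimated correlation). Per2 rose by 1.54 ± 0.23, Npas2 by 0.70 ± 0.10, Cry1 by 0.63 and Per3 by 0.44. Nr1d1 changed by −0.61 ± 0.12 and Dbp by −0.71 ± 0.14.

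The glucocorticoid response list rose in the unbound arrays of waking animals (2 of 15 called, mean 0.29, adjusted p = 0.000298; adjusted p = 0.484 with an estimated correlation), with Plin4 at 1.21 ± 0.16. So did the unfolded protein response list (0 of 17 called, mean 0.15, adjusted p = 0.00459; adjusted p = 0.484 with an estimated correlation). Oxidative phosphorylation genes fell, 8 of 29 with 0 rises (0 and 10 over the list alone). As a list they averaged −0.11 log2 (adjusted p = 6.24e-05; adjusted p = 0.324 with an estimated correlation). Quantile normalization within the fraction left 1 member and no call of the list (mean −0.05, adjusted p = 0.0544). Heat shock genes had 2 rises and 1 fall of 13 (adjusted p = 0.116), a list that passed after that normalization. Hspa1b (1.52 ± 0.35) was not called without the 3 animals (adjusted p = 0.0739). Myelin genes had 1 rise and 3 falls of 17 (mean −0.15, adjusted p = 0.772), with Opalin at −0.94 ± 0.18. Xist rose by 1.47 ± 0.44, a call lost after quantile normalization over all arrays (adjusted p = 0.0562) and with no intensity trend (adjusted p = 0.0638). Much of this rise lay in waking 3 and waking 5 (6.46 and 6.72 log2, other waking arrays 4.36 to 4.79, sleep arrays 3.53 to 4.04), and without the 3 animals it was 0.82 (adjusted p = 0.00224). The remaining waking and sleep values all lay below the unbound filter level of 5.183 log2. An offset between the groups cannot be told from a rise there. Means of the neuron, astrocyte, endothelium and apoptosis lists changed sign under scaling. Median, mean and test differed in sign for the astrocyte, endothelium, mural and sex-linked lists. Of the called genes 207 rose and 797 fell. After quantile normalization within the fraction 341 rose and 339 fell. The median of all genes was −0.09 log2. Relative to it the immediate-early list stood at 0.94, glucocorticoid response at 0.37, core clock at 0.25, unfolded protein response at 0.24 and oxidative phosphorylation at −0.02, and 533 genes were called without the 3 animals.

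**Figure D5:**
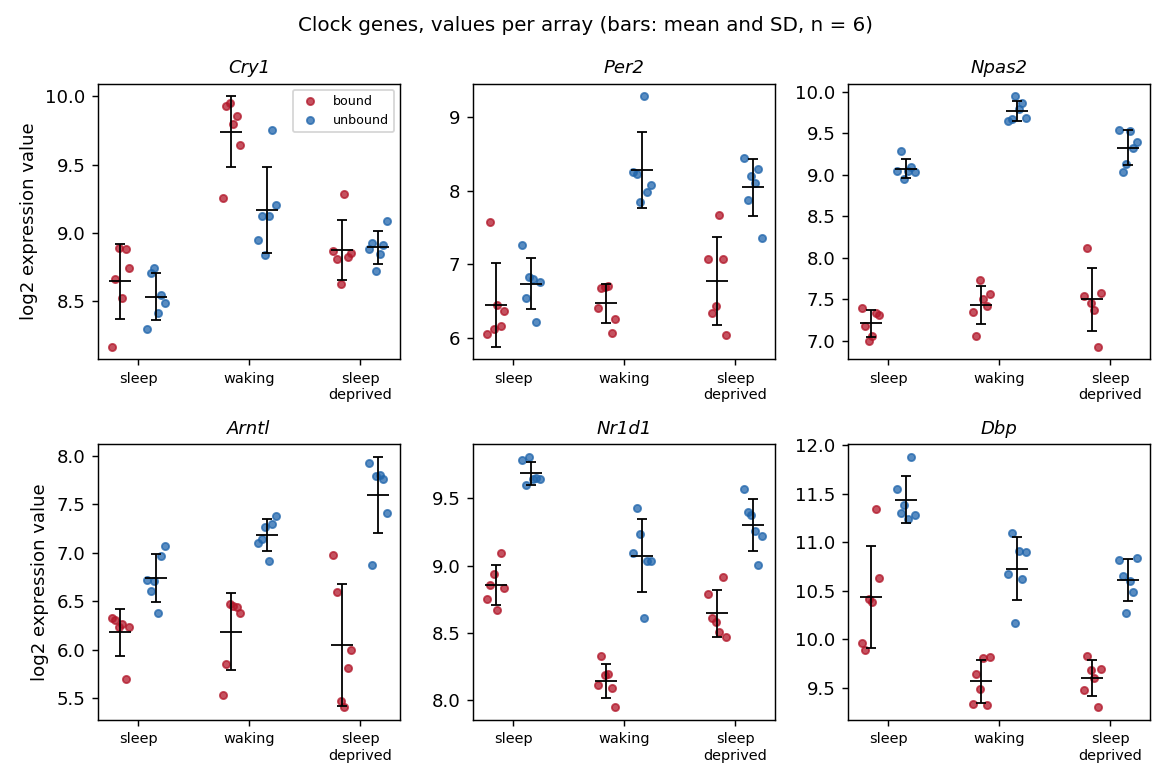
Levels of Cry1, Per2, Npas2, Arntl, Nr1d1 and Dbp on each array, with mean and SD of 6 arrays, by state and fraction. Npas2 in unbound sleep deprivation against waking changed sign with the mean of its probe sets.

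Unbound sleep deprivation against sleep compared the 2 groups of the light period in the unbound arrays. Egr2 rose by 3.21 ± 0.40 log2 (SE, n = 6 per group, adjusted p = 6.94e-05) and Plin4 by 2.92 ± 0.16 (adjusted p = 1.05e-09). Hspa1b rose by 2.74 ± 0.35 (adjusted p = 8.51e-05) and Fos by 2.58 ± 0.26 (adjusted p = 4.81e-06). Rad54l (−2.18 ± 0.60), Rimbp3 (−2.02 ± 0.46), Asap3 (−1.90 ± 0.17) and Srp54b (−1.89 ± 0.29) fell most. All 8 moved in their direction in 6 of 6 animals, and 7 showed no overlap. Of 20 immediate-early genes 13 rose and 0 fell (14 and 0 over the list alone). Their mean change was 1.16 log2 (adjusted p = 8.59e-21), with Arc at 2.35 ± 0.17, Nr4a1 at 2.13 ± 0.19 and Homer1 at 1.2 ± 0.09. Of 15 glucocorticoid response genes 11 rose and 0 fell (15 and 0 over the list alone). On average they moved by 1.07 log2 (adjusted p = 1.16e-18), with Cdkn1a at 1.96 ± 0.13 and Sgk1 at 1.11 ± 0.17. Of 13 heat shock genes 9 rose (10 over the list alone). The list's mean was 0.44 log2 (adjusted p = 4.85e-09; adjusted p = 0.0559 with an estimated correlation), and 5 were called after quantile normalization. Of 17 unfolded protein response genes 8 rose (13 over the list alone). As a list they averaged 0.44 log2 (adjusted p = 5.32e-08; adjusted p = 0.0764 with an estimated correlation), again with 5 after quantile normalization. Among clock genes 5 of 17 rose and 1 fell (9 and 2 over the list alone). Their mean change was 0.22 log2 (adjusted p = 0.0878; with fry, adjusted p = 0.0032), with Per2 at 1.31 ± 0.23, Arntl at 0.85 ± 0.17, Bhlhe40 at 0.53 ± 0.10 and Dbp at −0.83 ± 0.14. The myelin gene Mobp rose by 0.71 ± 0.08 and the astrocyte connexin gene Gjb6 by 1.32 ± 0.17. Median, mean and test differed in sign for the fatty acid and sphingolipid, myelin, lineage regulator, apoptosis and striatal lists. In total 647 genes rose and 442 fell, and 1078 were called without the 3 animals.

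Unbound sleep deprivation against waking gave 1177 higher and 207 lower genes. The median of all genes lay at 0.11 log2, and quantile normalization within the fraction left 284 higher and 298 lower genes, with the median at −0.0028. Changes of lists are therefore given relative to that median. The largest single rises were Rnf138rt1 (1.92 ± 0.25 log2, SE, n = 6 per group, adjusted p = 0.000197) and Skor1 (1.79 ± 0.39, adjusted p = 0.00846). Fosb (1.73 ± 0.39) and Ppp1r17 (1.75 ± 0.49) were not called without the 3 animals (adjusted p = 0.0533 and 0.199), and Ppp1r17 also lost its call after quantile normalization. Kcnq1ot1 (−1.65 ± 0.38), Srp54b (−1.64 ± 0.29), Pdlim3 (−1.57 ± 0.25) and the sialyltransferase gene St3gal1 (−1.54 ± 0.34) fell most. All 8 moved in their direction in 6 of 6 animals, and 4 showed no overlap.

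Relative to the median, glucocorticoid response genes were higher by 0.68 (11 of 15 higher and 0 lower, 12 and 0 over the list alone; adjusted p = 2.83e-10; adjusted p = 0.135 with an estimated correlation). After quantile normalization 7 remained called, with Cdkn1a at 1.64 ± 0.13 and Plin4 at 1.71 ± 0.16 before it. Heat shock genes were higher by 0.18 (10 of 13 higher; adjusted p = 1.14e-05; adjusted p = 0.145 with an estimated correlation; 2 after normalization). Unfolded protein response genes were higher by 0.18 (4 of 17 higher, 11 over the list alone; adjusted p = 0.0058; adjusted p = 0.484 with an estimated correlation; 1 after normalization). Oxidative phosphorylation genes stood only 0.03 above the median (13 of 29 higher, 21 over the list alone; adjusted p = 9.01e-08; adjusted p = 0.145 with an estimated correlation). Ribosomal protein genes stood 0.02 above it (7 of 20, 9 over the list alone; adjusted p = 0.000512; adjusted p = 0.324 with an estimated correlation). Neither of these 2 lists was called after quantile normalization (adjusted p = 0.136 and 0.889). Immediate-early genes stood 0.20 above the median (6 of 20 higher, 0 lower; adjusted p = 0.0689, called after that normalization; with fry, adjusted p = 0.00301). Myelin genes stood 0.11 above it (5 of 17 higher, 0 lower; adjusted p = 0.0689; with fry, adjusted p = 0.00535). Neuron genes (4 higher of 16) and core clock genes (2 higher and 2 lower of 17) moved from a mean of 0.09 to −0.03 and of 0.06 to −0.06 under normalization. The cell cycle, fatty acid, hypothalamic, mural, lineage regulator, precursor and phospholipid means changed sign too. Median, mean and test differed in sign for the clock, precursor, cell cycle, antigen presentation, endothelium, mural, hypothalamic and sex-linked lists. Without the 3 animals 710 genes were called.

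In the unbound arrays 269 genes changed the same way in waking and sleep deprivation, 93 higher and 176 lower (127 and 117 after quantile normalization). Egr2, Fos, Hspa1b, Arc (2.09 ± 0.17 and 2.35 ± 0.17 log2, SE, n = 6 per group), Sult1a1 (1.49 ± 0.28 and 1.57 ± 0.28), the clock gene Per2 (1.54 ± 0.23 and 1.31 ± 0.23) and Nr4a1 (1.30 ± 0.19 and 2.13 ± 0.19) rose in both. Chek2, Asap3 and Cfap52 fell in both. Independent lists would share 34.9 genes. Split sleep arrays gave 16 to 36, but with fewer control arrays per contrast, so this count cannot be set against the 34.9. Simulated unchanged groups shared 0, which sets no standard because they give almost no calls. The covariance was 0.059, which exceeded the 0.0195 simulated from the shared arrays by 0.0395. With split controls, which share no array, it was 0.0381. Waking stood apart from both other groups in 316 genes, 39 higher and 277 lower (61 and 63 after quantile normalization). Kcnq1ot1 and Kcne2 were among the higher and Skor1 and the chromatin gene Ezh2 among the lower ones. The calls of Kcne2 and Ezh2 were lost without the 3 animals (adjusted p = 0.0626 and 0.102 in waking against sleep), and that of Ezh2 also after quantile normalization (adjusted p = 0.0895). Independent lists would share 70.4 genes. Split waking arrays gave 9 to 24, again with fewer control arrays and so not comparable. The 0 of simulated groups again sets no standard. The covariance was 0.0378, which exceeded the 0.0196 simulated from the shared arrays by 0.0182. With split controls, which share no array, it was 0.0144. Without the 3 animals 175 genes changed the same way and 127 stood apart.

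The fraction difference asked whether a state change was larger in the bound than in the unbound arrays of the same animals. In waking against sleep, Plin4 rose by 2.37 ± 0.29 log2 more in the bound arrays (SE, n = 6 animals per state, adjusted p = 0.000148) and Scrg1 by 2.16 ± 0.30 (adjusted p = 0.000407), as did Hyls1 (2.22 ± 0.43). Btc changed by −3.20 ± 0.39 (adjusted p = 0.000148), Tfpi by −2.56 ± 0.55, Nfkbie by −2.54 ± 0.60 and St3gal1 by −2.23 ± 0.46 relative to the unbound arrays. Nrk (2.20 ± 0.61) and St3gal1 lost their calls without the 3 animals (adjusted p = 0.128 and 0.0597), and Nfkbie with the mean of its probe sets (adjusted p = 0.397). In sleep deprivation against sleep, Cdkn1a (2.63 ± 0.45, adjusted p = 0.00154), Zfand4 (3.07 ± 0.55, adjusted p = 0.00208), Nmrk1 (2.81 ± 0.49) and Myh11 (2.88 ± 0.79) rose more in the bound arrays. Tfpi (−3.23 ± 0.55), Mdrl (−2.86 ± 0.53), Btc (−2.84 ± 0.39) and Saxo2 (−2.48 ± 0.43) were lower. Myh11 was not called without the 3 animals (adjusted p = 0.08), nor Saxo2 with the mean of its probe sets (adjusted p = 0.255). All 8 genes moved in their direction in 6 of 6 animals in waking. In sleep deprivation 7 of 8 did and Myh11 moved in 5 of 6, and 4 and 6 genes showed no overlap.

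Heat shock genes rose more in the bound arrays in both contrasts. In waking 9 of 13 did and 0 the other way (10 and 0 over the list alone), by 0.66 log2 on average (adjusted p = 2.59e-07; adjusted p = 0.0799 with an estimated correlation). In sleep deprivation 8 did and 0 the other way (9 and 0 over the list alone), by 0.61 log2 (adjusted p = 2.59e-07; adjusted p = 0.0799 with an estimated correlation). Glucocorticoid response genes rose more in the bound arrays of sleep deprived animals, 8 of 15 with 1 the other way (9 and 1 over the list alone; 0.85, adjusted p = 1.52e-06; adjusted p = 0.0799 with an estimated correlation). Fkbp5 stood at 2.16 ± 0.30 and Zbtb16 at 2.05 ± 0.31, and the list was not called by camera in waking (0.44, adjusted p = 0.0981; with fry, adjusted p = 0.0172). Arc rose less in the bound arrays in both contrasts (−1.52 ± 0.21 and −1.82 ± 0.21). The immediate-early list was not called by camera in either (−0.15, adjusted p = 0.174 in waking; −0.35, adjusted p = 0.113 in sleep deprivation, where fry gave adjusted p = 0.00851). In waking, fry also passed the microglia (adjusted p = 0.00247), hypothalamic (0.0117), lineage regulator (0.029), striatal (0.029) and mural lists (0.0459), none called by camera. In sleep deprivation it passed the cholesterol (adjusted p = 0.00635), core clock (0.00986) and sex-linked lists (0.0191). In all 744 genes differed in waking, 549 higher and 195 lower in bound, which became 334 and 266 after quantile normalization within the fraction. In sleep deprivation 869 differed, 422 higher and 447 lower. Without the 3 animals 384 and 697 genes were called. In waking, second probe sets moved the same way in 67.3% of 165 called genes and in 54.3% of the 35 changed at least 2-fold, against 59.9% of uncalled genes, a limit of the large changes. In sleep deprivation they did in 76.5% of 217 called genes and 73.8% of the 65 changed at least 2-fold, against 59.5%.

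Camera, which compares a list with all other genes, called no list of neuron, astrocyte, microglia, endothelium, mural, choroid plexus, striatal or hypothalamic genes between states in either fraction. With fry, which does not make that comparison, microglia (adjusted p = 0.00879), striatal (0.00535), choroid plexus (0.0495) and hypothalamic genes (0.0495) passed in unbound waking against sleep. Neuron (adjusted p = 0.0172), astrocyte (0.0469), microglia (0.0469) and striatal genes (0.00749) passed in unbound sleep deprivation against waking. So did phospholipid (adjusted p = 0.0107 and 0.000905) and lineage regulator genes (0.0311 and 0.0207) in these 2 contrasts, and ribosomal (0.0128) and antigen presentation genes (0.0148) in the first. In both contrasts the median of all genes was itself off 0, at −0.09 and 0.11 log2. Some lists that camera called did not pass with fry: unfolded protein response and glucocorticoid response in bound waking against sleep (adjusted p = 0.213 and 0.105) and in unbound waking against sleep (0.178 and 0.108), and unfolded protein response in bound sleep deprivation against waking (0.071).

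Sex-linked genes set 3 animals apart, waking 3, waking 5 and sleep deprived 11. Eif2s3y was at least 3.78 log2 lower and Xist at least 0.365 log2 higher in them than in the other 15 animals, in both fractions. Without them 11357 genes were called between the fractions, and the other counts are given with their comparisons. The animals were chosen after the data had been seen, and no sleep animal was among them.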

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

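Of the tests in this part, those of the second probe sets, the first count without 3 animals and the random splits were written down before their own results were computed, and all others were chosen only after the result was seen. The 3 animals themselves were found in the data.

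The first pattern weighed was the link of state calls to dim probe sets and to the scale of the arrays, which separate processing of each group could produce. Of probe sets of genes not expressed in brain, 38.1% reached an unadjusted p under 0.05 in bound waking against sleep and their changes did not correlate between the fractions (r = −0.0625), so offsets between groups are a likely cause of calls among dim probe sets. Array scale is left open for the excess of lower values in unbound waking arrays, since the change of 18 hybridization spikes (−0.0231 log2, 95% interval −0.125 to 0.0785) has an interval that includes both 0 and the change of genes of the same level (−0.0746). For genes changed the same way in bound waking and sleep deprivation, the mean of the 2 changes was taken in the second probe set. It had the same direction in 158 of 183 genes, 86.3% (95% interval 80.5 to 91%). Among uncalled genes 60.1% of second probe sets moved the same way in each single contrast, which is a different measure. The 86.3% argues against offsets as the whole cause for those 183 genes only, whose second probe sets passed the level filter. The other genes of that set were not covered. The prediction for offsets also asked for unexpressed probe sets to be called at least as often as bright ones, and they were (23.2% and 9.77% in bound waking against sleep). Random splits of the arrays gave at most 35, 132 and 6 genes in the 3 bound state contrasts (1318, 2005 and 698 observed). In the unbound ones they gave at most 6, 5 and 11 (1004, 1089 and 1384), and in the fraction differences 2 and 2 (744 and 869). Chance can be excluded for these contrasts, as for bound against unbound (11642 against at most 8457). An offset of a whole group would pass this test too. For the bound and unbound sets changed the same way (699 and 269) or set apart (174 and 316) the splits gave 0. Such splits give few calls in either contrast, so this 0 sets no standard for an overlap of 2 contrasts.

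The second pattern was the rise of stress and activity genes in the bound arrays, which unbound RNA carried into the immunoprecipitate could produce. Carried-over RNA in a share that stays the same between states would alone give no larger change in the bound than in the unbound arrays. The heat shock list, however, rose more in the bound arrays by 0.606 log2 in sleep deprivation (95% interval 0.243 to 0.969, exact permutation p = 0.0152). It did not in animals 8 and 11 (−0.008265 and −0.2725 bound minus unbound, sleep animals −0.5568 to 0.01481). The glucocorticoid response list rose more by 0.849 (0.512 to 1.19, exact permutation p = 0.00216). For these 2 lists the values argue against such carry-over as the whole cause. A share that changed with state and an offset of a whole group were not tested. A response of oligodendrocytes themselves is a hypothesis that was not tested either. The immediate-early list rose less in the bound arrays in sleep deprivation (−0.35 log2, −0.54 to −0.159, exact permutation p = 0.00433), and in waking the difference was −0.149 (−0.348 to 0.0493, exact permutation p = 0.126), so carry-over may contribute to this list and the test leaves it open, as it does for the unfolded protein response list (0.0226 in sleep deprivation, −0.0885 to 0.134, exact permutation p = 0.671; 0.0394 in waking, exact permutation p = 0.457). Its members differed, with Arc at −1.82 log2 in sleep deprivation and Fos at −0.00735.

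The third pattern was the sex of 3 animals, since waking 3, waking 5 and sleep deprived 11 had Eif2s3y at least 3.78 log2 below the other animals and Xist at least 0.365 log2 above them in the bound and 1.67 in the unbound arrays. The rule set for mixed sex asked for a gap of 3 log2 in the Y-linked genes and in Xist, which Kdm5d reached (5.74 bound, 5.06 unbound) but Uty (1.81 and 2.55) and Xist did not, so mixed sex cannot be told by that rule. The rule was strict for Uty, which lay as low as 5.16 log2 in the other animals. In the 3 animals Eif2s3y, Uty and Kdm5d all lay at 2.59 to 3.90 log2 in both fractions. Genes not expressed in brain had a median of 3.03 log2 over all arrays, so Y-linked signal was near background in these animals. In the other 15 animals Eif2s3y lay at 7.08 to 9.15 log2 and Kdm5d at 8.92 to 9.94. These values argue against all 18 animals being male, although the rule above did not decide it. The first test asked whether the bound count of genes changed the same way stayed within 1.5 times without these animals; it fell from 699 to 403, 1.73 times lower, but the test set 3 animals left out against 1 and did not match the number of animals, so it leaves an effect of sex open. Against 30 other sets of 2 waking and 1 sleep deprived animals, a comparison chosen after that result, 403 lay between their lowest count of 370 and their median of 458.5, so the loss may come from fewer animals. By the same comparison the count for waking set apart (45) lay below all other sets (64 to 120), as the prediction for sex asked. Those sets share animals and hold only 6 other pairs of waking animals, and several counts were compared, so sex is not established as its cause. An effect of sex cannot be told for bound waking against sleep (684, other sets 719 to 1226). There only 6 other pairs of waking animals could be compared, and the pair left out is lowest by chance in 14.3%. It also cannot be told for sleep deprivation against waking (234, other sets 217 to 441). Nor can it be told for sleep deprivation against sleep, where 1799 lay above the median of 1731 that had been set as the threshold but inside the spread of the other sets (1537 to 1976).

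Arrays that lay far from the other 5 of their group were flagged 12 times in 150 groups of list means and array means, where chance flags about 1 in 20. In the bound waking arrays, replicate 1 was low in core clock genes (8.265 log2, others 8.322 to 8.352) and high in heat shock genes (11.26, others 11.05 to 11.1), replicate 2 high in apoptosis genes (7.898, others 7.496 to 7.645), replicate 6 high in microglia genes (6.337, others 5.636 to 5.87), and replicate 5 had the highest array mean (5.942, others 5.925 to 5.931). Unbound waking replicate 3 was low in fatty acid and sphingolipid genes (8.819, others 9.11 to 9.284) and in myelin genes (9.625, others 9.9 to 10.02). Among sleep deprived animals, bound replicate 10 was low in cell cycle genes (6.861, others 7.045 to 7.149), bound replicate 6 in choroid plexus genes (5.804, others 6.215 to 6.425), bound replicate 11 in striatal genes (7.46, others 7.745 to 7.9), and unbound replicate 8 was high in mural genes (7.832, others 7.082 to 7.344). Bound sleep replicate 5 was low in striatal genes (7.216, others 7.606 to 7.774).

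State changes that differed between the fractions by a test of the difference numbered 744 genes in waking and 869 in sleep deprivation. In waking the named genes were Plin4 (2.37 log2), Hyls1 (2.22), Nrk (2.20), Scrg1 (2.16), Btc (−3.20), Tfpi (−2.56), Nfkbie (−2.54) and St3gal1 (−2.23). In sleep deprivation they were Zfand4 (3.07), Myh11 (2.88), Nmrk1 (2.81), Cdkn1a (2.63), Tfpi (−3.23), Mdrl (−2.86), Btc (−2.84) and Saxo2 (−2.48). The lists were heat shock in waking (0.657) and in sleep deprivation (0.606) and glucocorticoid response in sleep deprivation (0.849), each with adjusted p = 0.0799 with an estimated correlation.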

How the results depend on the processing

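Leaving out the 3 animals was chosen after seeing the data, and all other alternatives were fixed before the data were examined. Without a filter, more genes were tested and counts rose to 2819, 3551 and 2124 in the 3 bound state contrasts (waking against sleep, sleep deprivation against sleep and against waking), 1383 and 670 for bound genes changed the same way and set apart, 2382, 2482 and 2771 in the unbound contrasts, 775 and 866 for the unbound sets, and 2071 and 2253 for the fraction differences, including genes whose signal lies near background. With the stricter filter fewer genes were tested, which left 734 in bound waking against sleep, 277 in sleep deprivation against waking, 443 the same way and 52 apart, 628 in unbound waking against sleep, 679 in sleep deprivation against sleep, 144 the same way and 178 apart, and 285 and 416 in the fraction differences. Quantile normalization over all or within a fraction gave 584 and 582 in unbound sleep deprivation against waking and 128 and 124 for unbound waking apart, by making the arrays' distributions equal. Leaving out the 3 animals, which also lowers the number of animals, left 684, 234, 403 and 45 in bound waking against sleep, sleep deprivation against waking, the same way and apart, 533, 710, 175 and 127 for the same 4 unbound results, and 384 in the fraction difference in waking. The sleep and waking animals share only a replicate number: deviations of same-numbered animals correlated by −0.000946 to 0.0868 (bound) and −0.00503 to 0.1 (unbound), and 2 and 3 of 6 matched best with their own number. With that number as a replicate block, bound waking against sleep gave 1303 genes and unbound 464, and the cause was not tested. Leaving out each array in turn gave 990 to 1473, 1648 to 2083 and 532 to 704 genes in the bound contrasts, 532 to 704 the same way and 119 to 172 apart, and 748 to 1007, 847 to 1282, 989 to 1513, 211 to 261 and 234 to 324 for the unbound results. The mean of all probe sets of a gene reversed 13 single changes, whose cause was not tested: Sc5d in bound waking against sleep (0.00133 log2), Chka (−0.0913) and Sptlc1 (0.169) in bound sleep deprivation against sleep, Col5a1 in unbound waking against sleep (−0.092) and sleep deprivation against waking (0.00113), Ndufb8 in unbound sleep deprivation against sleep (−0.179), Agpat4 (−0.035), Cryab (−0.0535), Ddit3 (−0.495), Npas2 (0.121) and Rps4x (−0.0615) in unbound sleep deprivation against waking, and Ddit3 (−0.456) and Eif2s3y (−0.593) in bound against unbound. Of 4673 alternative values of 537 named gene results, 4190 kept direction and call, 470 lost the call and 13 reversed. Of 164 alternative values of 41 list results, 113 were unchanged, 42 lost the call, 9 gained it and 0 reversed. Camera called 37 of the 41, and the estimated correlation alone ended 29 of these calls and kept 8.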

Other observations

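The values in this part were compiled only after the state results were seen, and no further test was run on them apart from the interval given for the spikes. Changes in the 2 fractions overlapped more than independent lists would: 37 genes rose in waking against sleep in both (9.68 by independence) and 85 fell (38.2), while 35 rose in bound and fell in unbound and 7 the reverse, with r = 0.156 over all genes, and in sleep deprivation against sleep 166 rose (48.7) and 82 fell (30.4), 25 and 24 went opposite ways, with r = 0.24. In sleep deprivation against waking 71 were higher in both (31.7) and 14 lower (4.8), 9 and 11 went opposite ways, with r = 0.0758. Each pair of fractions came from the same animals.

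Spike-in control probe sets moved little in either fraction. The median change of 18 such probe sets was 0.0465 log2 in unbound sleep deprivation against waking, where the median of all genes was 0.111, and −0.026 in waking against sleep, where it was −0.0875. The mean spike change in that second contrast, −0.0231, had a 95% interval over arrays that included 0 (−0.125 to 0.0785). In the bound arrays the spike-in medians were −0.00177, 0.0286 and 0.0317 in the 3 contrasts, against gene medians of −0.0127, −0.0078 and 0.013.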
